A study of Electrophorus voltai with 3 samples.

How the data were processed

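Spatial gene expression was measured with the Visium 3' assay in 3 sections of 1 group, muscle tissue of the main electric organ of Electrophorus voltai, frozen, embedded and sectioned at 10 µm per the labels' protocols. Per the submitters' processing notes, reads were processed with Space Ranger 1.3.1 and STAR; per the file headers, the matrices of spots over tissue came from Space Ranger 1.2.1, and this difference could not be settled here. The genome build, the annotation and the treatment of reads shared between similar genes are not given in the sources used here, so genes with near-identical copies are uncertain. The deposited values used are raw UMI counts per gene and spot, not normalised, for the 4992 array positions of each section and separately for the spots over tissue; both held identical counts for the same spots. The authors' position tables gave each spot's row, column and whether it lay over tissue. The images were not used here.

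The files list 23221 gene identifiers and pair 0 of them with a symbol. The 21 gene lists fixed beforehand (muscle, ion channel, synapse, metabolism and other cell type markers) could therefore not be matched, and comparisons of lists, their co-location and their share of UMIs were not made. Named genes were to be those past the test, changed the same way in all 3 sections and with at least 50 CPM in the region or the rest, and a gene without a symbol only if first in its ranking. That leaves the highest and the lowest gene of each region, the gene with the highest Moran's I and the most abundant gene. The tests, their samples and the alternatives were fixed before the data were examined, except those named as later below.

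Genes were divided at random (seed 1) into 11610 for clustering and 11611 for testing. Tissue spots of all sections were log-normalised to the median total, each gene centred within its section, and the 1000 most variable genes of the clustering set reduced to 20 principal components (scikit-learn 1.9.0). A graph of 15 neighbours, weighted by shared neighbours, was divided with the Leiden method at resolution 0.4 (leidenalg 0.10.2, igraph 0.11.9). Of 6 regions, the 5 with at least 30 spots in every section were tested, with 8256 of 8317 tissue spots. Spots with few UMIs were kept.

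UMI counts of the testing set were summed per section and region, since spots are not replicates, giving 15 sums of 123904 to 1914953 UMIs. The sums were filtered with filterByExpr, scaled with TMM and fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, 1 coefficient per region and the section as a block, 8 residual degrees of freedom, estimated common dispersion 0.00176). A test over all regions, a contrast of each region with the mean of the other tested regions and contrasts of pairs were adjusted by Benjamini-Hochberg. Standard errors were taken from the log2 difference and its F statistic. The section was a block because sums of the same section share its capture and library. Levels are TMM-scaled CPM of the tested genes, so they exceed CPM of all genes. DESeq2 1.42.0 was the alternative test.

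Moran's I was computed per gene and section on log-normalised counts with the 6 adjacent positions as neighbours, for genes with a UMI in at least 5% of the spots of every section. Genes were called by size, not by a p-value. Precision was set by depth: 3 UMIs, the most that a count of 0 allows at 95% confidence, equal 0.279, 0.278 and 0.282 CPM in the 3 sections.

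Several measures were chosen after seeing the data. These were the long axis of a region, from the autocorrelation of its spots at lags of 2 to 5 spacings, for which 2 other measures had been tried first, and the minimum Jaccard overlap of 0.3 for matching regions. The same holds for clustering after thinning every spot to 2505 UMIs, the 10th percentile, which left out 831 spots, and for fits with interior spots only (7621 spots), with library size alone, without region 5 or without the section 3 spots under 500 UMIs. The other alternatives were edgeR's RLE size factors, no low-count filter, no section block, each section left out, resolutions of 0.2 and 0.8, no centring, exchanged gene sets, UMIs divided binomially between clustering and testing, and spots with at least 500 UMIs. For Moran's I they were 18 neighbours, thresholds of 0.05 and 0.2, Pearson residuals, 1% of spots, thinned spots and, chosen later, spots with at least 500 UMIs.

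The fit was tested on simulated sums of arbitrary blocks of spots in each section, not of the regions found here. For 1 block against the others, the genes for testing were simulated with a dispersion of 0.005, and 3089 of them passed the count filter. The fit recovered 22%, 68%, 88% and 98% of genes changed 1.25, 1.5, 2 and 4-fold (50 of each), and 4.17% of the calls were false. These genes changed in that block only, whereas 65.4% of the tested genes differed between the real regions. The recovered and false shares therefore need not hold for the real contrasts. Spots simulated without regions gave 1 region, so no comparison could be made of them. Moran's I passed 0.1 for 0% of 200 random patterns and for 100% of 200 gradients and 200 banded patterns. These patterns were normally distributed values of a fixed strength in section 1, not counts. They therefore do not show how often a pattern in a gene with few UMIs would pass.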

Results

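Spatial transcriptomes were collected from 3 sections of frozen muscle tissue of the main electric organ of Electrophorus voltai, an electric eel. The main organ is built of stacked electrocytes, large cells of muscle origin whose discharges add up to the strong electric pulse of the animal. Each 10 µm section lay on a capture area of barcoded spots, and each spot may cover parts of several cells. The values were counts of unique molecular identifiers (UMIs), which count captured RNA molecules per gene and spot. All 3 sections formed 1 group, so the comparison that the design allows was between parts of the same sections. The labels do not say whether the sections came from more than 1 animal. The p-values measure how region differences varied over these sections, after differences between whole sections were removed. That variation may be technical.

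Sections 1, 2 and 3 had 2677, 2862 and 2778 spots over tissue and 10744554, 10789536 and 10643336 tissue UMIs. The median spot held 3793, 3567.5 and 3607 UMIs and 1244, 1178 and 1206 genes. At this depth 1 UMI in a whole section corresponded to 0.0931, 0.0927 and 0.0940 CPM (counts scaled to the same total in every sample). Of 23221 annotated genes, 11466, 11908 and 11347 had at least 1 tissue UMI. The 10 most abundant genes took 18.4%, 17.6% and 18.9% of tissue UMIs, and the 100 most abundant took 48.0%, 49.4% and 48.2%. The most abundant gene, gene-Evo03696, took 3.61% ± 0.45 of UMIs (SD, n = 3). The log2 CPM of sections correlated at Pearson's r of 0.993, 0.995 and 0.992 for sections 1 and 2, 1 and 3, and 2 and 3, across genes, which are not independent replicates. Between the same pairs, 6.10%, 2.71% and 7.03% of genes with at least 20 UMIs differed more than 1.5-fold, so section 2 differed more from sections 1 and 3 than these did from each other.

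The files give 0 of the 23221 identifiers a gene symbol, and the genome build is not given in the sources used here. Genes are therefore named by identifier, and only where a gene came first in a ranking.

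The tissue divided into 5 regions that were large enough to test, numbered by size, and spots of the same region lay together more than shuffled labels would place them. Region 1 held 36.2% ± 2.0 of tissue spots (SD, n = 3 sections throughout), region 2 held 35.2% ± 3.2, region 3 held 18.4% ± 1.5, region 4 held 7.23% ± 0.61 and region 5 held 2.36% ± 0.33. In region 4, 44.5% ± 3.5 of adjacent spots belonged to the same region, against 7.34% after region labels were shuffled over the spots. The same share was 53.9% ± 4.4 against 36.2% in region 1, 45.5% ± 4.2 against 35.2% in region 2, 44.8% ± 4.9 against 18.4% in region 3 and 27.5% ± 8.0 against 2.33% in region 5. Region 5 lay along the margin: 65.5% ± 9.7 of its spots had an adjacent position off tissue, against 2.32% ± 0.70 in region 1.

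**Figure D1:**
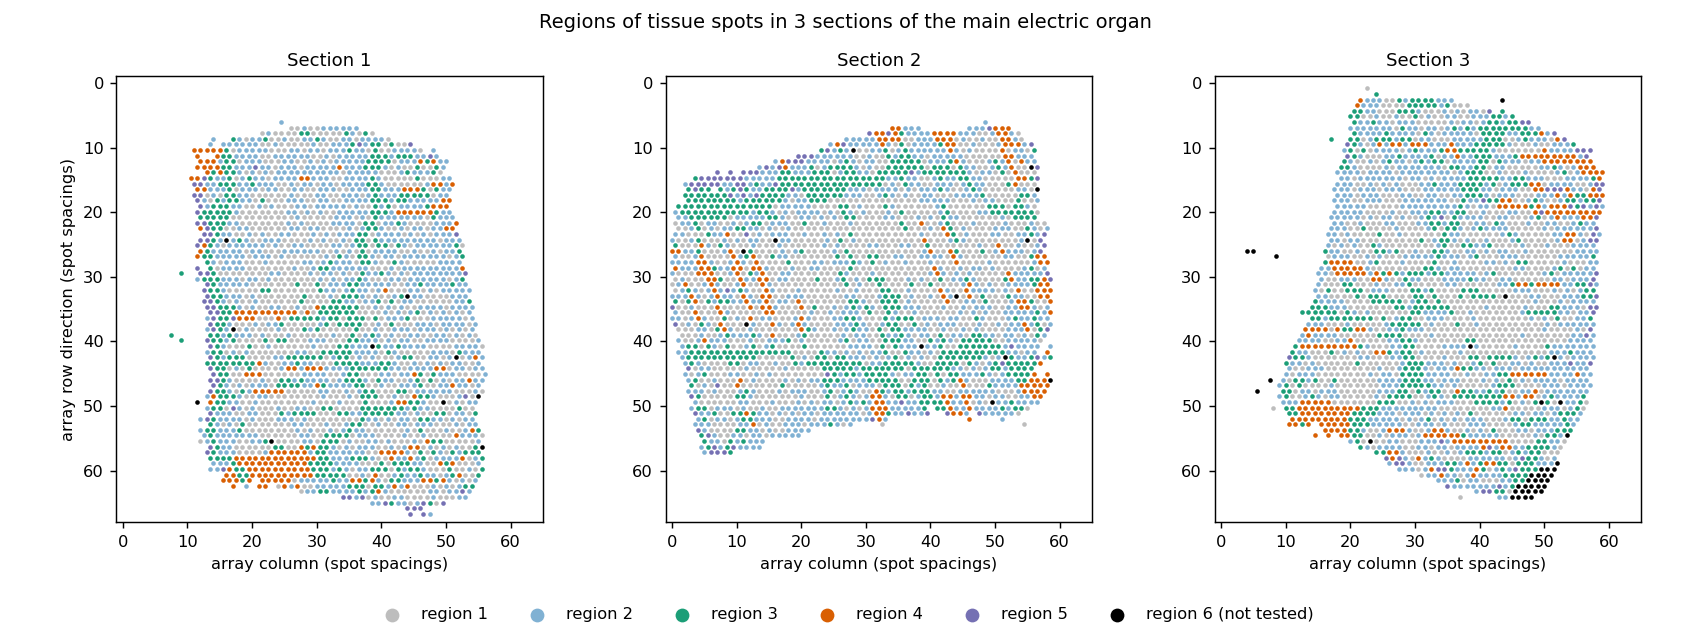
Each point is a tissue spot at its position on the array, in spot spacings, coloured by region, with 1 panel per section. Region 4 (orange) forms narrow lines and a few blocks, region 3 (green) forms bands at an angle to those lines, and region 5 (purple) follows parts of the margin. The black patch in section 3 belongs to region 6, which was not tested.

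Regions 3 and 4 were elongated in different directions. In region 4 the spatial autocorrelation at 2 to 5 spot spacings was 0.266 ± 0.070 along its long axis and 0.087 ± 0.012 across it. In region 3 it was 0.158 ± 0.049 along and 0.029 ± 0.027 across. The difference between both directions exceeded the highest of 100 shuffles in all 3 sections for both regions and for region 5, while region 1 exceeded it in 0 sections and region 2 in 1. Shuffling removes the clumping of spots as well as their direction, so it is a low bar. The long axes of regions 3 and 4 met at 71.4, 74.2 and 64.4 degrees in sections 1, 2 and 3, a mean of 70.0 ± 5.1 degrees, although both axes lay at other angles on the array in section 2. When spots were thinned to equal UMIs and clustered anew, the angle was 36.0 ± 27.2 degrees, so the angle between regions 3 and 4 depended on this choice. In the other 8 alternatives it lay between 62.8 and 78.5 degrees. The angle describes direction only. Contacts between spots of regions 3 and 4 were 0.511 ± 0.167 of the shuffled mean, below all 100 shuffles in 3 sections. Those of regions 1 and 4 were similar, at 0.479 ± 0.060.

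Region 4 spots held the most UMIs and region 1 spots the fewest different genes at equal depth. The median was 5754 ± 214 UMIs per spot in region 4, 4611 ± 510 in region 5, 4231 ± 232 in region 3, 3506 ± 163 in region 1 and 3399 ± 106 in region 2. With each spot thinned to 2505 UMIs, region 1 had 907 ± 17 genes per spot, region 2 had 975 ± 5, region 4 had 1034 ± 15, region 3 had 1046 ± 4 and region 5 had 1086 ± 13; without thinning, the medians were 1121 ± 54, 1181 ± 31, 1733 ± 63, 1434 ± 47 and 1618 ± 130. Thinning left out 290, 368, 12, 93 and 7 spots of regions 1, 2, 4, 3 and 5. The 10 highest genes of each region took 20.5% ± 0.4 of UMIs in region 1, 18.99% ± 0.70 in region 2, 14.5% ± 0.9 in region 3, 19.1% ± 0.1 in region 4 and 17.2% ± 0.7 in region 5. No test was made of these values: the ranges of regions 1 and 4 did not overlap for UMIs or thinned genes.

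**Figure D2:**
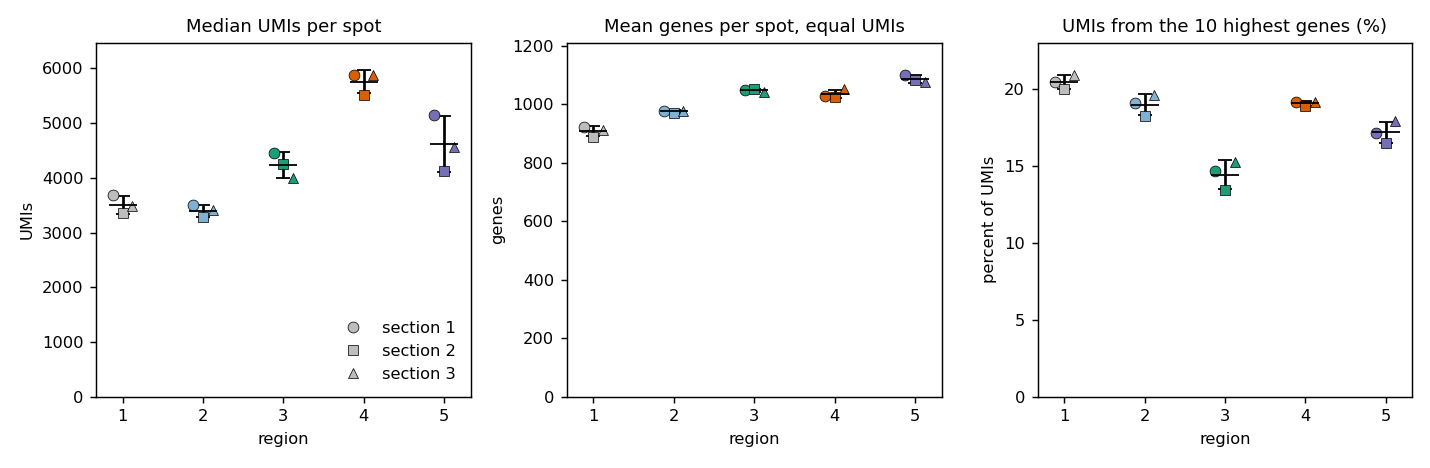
Median UMIs per spot, mean genes per spot after thinning to 2505 UMIs and percent of UMIs from the 10 highest genes, by region, on axes that start at 0. Points are the 3 sections, and black bars give the mean ± SD; region 4 lies highest in UMIs at 5754 and region 3 lowest in the share of the 10 highest genes at 14.5%.

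The borders of the regions varied with the clustering, and regions 1, 3 and 4 found a match of at least 0.3 in all of 7 other clusterings. A larger region that takes in others can also reach 0.3, so a match does not show that a region was kept. At resolution 0.2 the match of region 1 held 100% of its spots, but also 58.1% of the other spots. After thinning, the match of region 2 held 62.8% of its spots and 55.2% of the others. The best match of region 4 shared 0.469 to 0.965 of the joint spots (Jaccard overlap), region 3 shared 0.387 to 0.730, region 1 shared 0.476 to 0.662 and region 2 shared 0.299 to 0.595. Region 5 reached 0.3 in only 1 of the 7, at a finer resolution, with an overlap of 0.649. Over the alternatives with a match, the share of spots ran from 18.5% to 73.3% for region 1, 22.6% to 73.3% for region 2, 7.14% to 28.8% for region 3 and 6.53% to 13.3% for region 4. Region 6 held 10, 12 and 39 spots with median UMIs of 308, 283 and 27, and was not tested.

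Of 3384 genes that passed the count filter and were tested, none of which had been used to cluster the spots, 2213 (65.4%) differed between regions at an adjusted p under 0.05 in edgeR's quasi-likelihood F test with the section as a block. Without the count filter 2203 of 6715 genes (32.8%) differed. The test used 15 sums of UMIs, 1 per section and region, and the residual variation, after differences between sections were removed by the block, was 4.20% (biological coefficient of variation). Among the 2213 genes, the highest level was in region 1 for 680, region 3 for 599, region 4 for 468, region 5 for 393 and region 2 for 73. This ranks fitted levels under TMM without a test of their order. Region 5, with the fewest UMIs, was highest for 393 of these genes and also lowest for 540. Only 165 and 290 genes were called higher and lower there than in the mean of the rest. Compared in pairs, regions 1 and 3 differed in 1762 genes, the most of the 10 pairs, and regions 4 and 5 in 350, the fewest. These counts depend on the UMIs of each region as well as on the size of change: the median absolute log2 change of the called genes was 0.65 between regions 4 and 5, 0.63 between regions 1 and 3, 0.77 between regions 1 and 5, the largest, and 0.34 between regions 1 and 2, the smallest. Regions 1 and 2, which together held most spots, differed in 643 genes, of which 24 changed more than 2-fold. Regions 3 and 4 differed in 1252 genes, 663 higher in region 3 and 589 higher in region 4, and 356 of them changed more than 2-fold.

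Region 1 was set against the mean of the other 4 regions, as was each region below. The genes named for each region are first among called genes with at least 50 CPM in the region or the rest and the same direction in all 3 sections, and rarer genes changed more in several regions. The log2 difference is from the mean of the log levels of the other 4 regions, whereas the CPM given for them is their arithmetic mean, so the ratio of both CPM values is not the fold change. In region 1, 820 genes were higher and 694 lower, and 106 and 60 of them by more than 2-fold. The gene with the highest increase at 50 CPM or more, gene-Evo21495, had 68.5 ± 18.2 CPM in region 1 and 14.3 ± 3.3 in the other regions (log2 difference 2.504 ± 0.194 SE, adjusted p = 4.51e-28 by edgeR, higher in 3 of 3 sections). It declined over regions 2, 3, 4 and 5 to 24.9, 17.5, 8.82 and 5.84 CPM. The gene with the largest decrease at 50 CPM or more, gene-Evo15267, had 25.7 ± 4.1 CPM against 54.3 ± 5.9 (log2 difference -1.04 ± 0.17 SE, adjusted p = 1.64e-08 by edgeR, lower in 3 of 3 sections) and was highest in region 4, at 71.1 ± 18.01 CPM. The balance of directions depended on the scaling: with library size alone in place of TMM, 279 genes were higher and 2007 lower, a share of higher genes of 12.2% against 54.2%. That scaling moved the median log2 difference of all genes by -0.39, -0.11, 0.13, 0.10 and 0.27 in regions 1 to 5, so directions are relative to TMM.

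Region 2 differed least in size from the mean of the rest, with a median of 0.30 log2 units among its called genes, and 394 genes were higher and 157 lower, 13 and 8 of them by more than 2-fold. Its leading gene at 50 CPM or more, gene-Evo09192, had 53.0 ± 10.3 CPM against 28.6 ± 3.6 (log2 difference 1.27 ± 0.18 SE, adjusted p = 1.84e-09 by edgeR, 3 of 3 sections), and its level in region 1 was higher still, at 64.96 ± 9.94 CPM. Of the genes at 50 CPM or more, the largest decrease was that of gene-Evo07386, which had 27.6 ± 5.7 CPM against 62.0 ± 12.2 (log2 difference -0.85 ± 0.17 SE, adjusted p = 1.38e-05 by edgeR, 3 of 3 sections); it was highest in region 3, at 132 ± 36 CPM. Without the section block 160 genes were called in region 2, with DESeq2 350, and without section 1 or section 3 the counts were 285 and 334. With library size alone 180 were higher and 500 lower, 26.5% higher against 71.5%.

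Region 3 had 708 higher and 641 lower genes, with 174 and 30 of them beyond 2-fold, the most increases of that size of the 5 regions. Its leading gene at 50 CPM or more, gene-Evo17936, had 169 ± 198 CPM against 19.7 ± 18.9 (log2 difference 3.09 ± 0.15 SE, adjusted p = 4.32e-55 by edgeR, higher in 3 of 3 sections). The level of gene-Evo17936 was set by section 1, with 396 CPM in region 3 against 33.7 and 78.4 in sections 2 and 3. Without section 1 the log2 difference was 3.97. Region 5 had 0 CPM of this gene in sections 2 and 3, so that size depends on the prior count. With region 5 left out of the fit over all sections, the log2 difference was 2.99. Of the genes at 50 CPM or more, gene-Evo02848 decreased most and had 31.8 ± 3.3 CPM against 164 ± 34 (log2 difference -1.73 ± 0.15 SE, adjusted p = 1.23e-23 by edgeR, 3 of 3 sections). It was concentrated in region 4, at 458 ± 119 CPM, which carries the mean of the rest, and stood at 55.3 to 80.6 CPM in regions 1, 2 and 5. With library size alone 1031 genes were higher and 417 lower in region 3, 71.2% against 52.5%.

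Region 4 had 515 higher and 556 lower genes, 101 and 44 of them beyond 2-fold. Its leading gene at 50 CPM or more, gene-Evo00003, had 107 ± 44 CPM in region 4, 12.003 ± 3.515 in region 1, 9.94 ± 3.66 in region 2 and 3.61 ± 1.62 in region 3 (adjusted p = 5.37e-46 by edgeR, 3 of 3 sections). In region 5 it had 0 UMIs, which allows up to 5.70 CPM over the 3 sections, so the fitted log2 difference of 5.27 ± 0.29 depends on the prior count. The log2 difference was 3.801 with region 5 left out of the fit, 3.91 among interior spots, where region 5 was not tested, and 2.73 after thinning before clustering, the lowest of 16 alternatives. At 50 CPM or more the largest decrease was that of gene-Evo17936, with 12.5 ± 13.51 CPM against 59.0 ± 64.7 (log2 difference -1.57 ± 0.34 SE, adjusted p = 4.19e-05 by edgeR, 3 of 3 sections). This call was lost without section 1, where the log2 difference was -0.49 with an adjusted p of 0.946 by edgeR, over a range of 5.45e-11 to 0.946 in 16 alternatives. Region 5 had 0 CPM in sections 2 and 3, which lowers the mean log level of the rest. Region 4, at 6.91 and 2.61 CPM there, still lay below region 1 (20.9 and 9.25), region 2 (16.1 and 15.2) and region 3 (33.7 and 78.4). Those levels of region 4 rest on few UMIs. No fit left out both section 1 and region 5, so whether the 0 CPM of region 5 explains the lost call is not decided. With region 5 left out of the fit over all sections, which still held section 1, the log2 difference was -1.97 (adjusted p = 5.45e-11 by edgeR). Without the section block it was -1.65, near the reported -1.57, and the adjusted p was 0.240 by edgeR. Without section 3, 707 genes were called in region 4, and with library size alone 710 were higher and 383 lower, 64.96% against 48.1%.

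Region 5, the marginal region, had 165 higher and 290 lower genes, 27 and 38 of them beyond 2-fold. The leading gene at 50 CPM or more, gene-Evo03677, had 56.4 ± 5.9 CPM against 22.4 ± 1.9 (log2 difference 1.37 ± 0.33 SE, adjusted p = 0.000986 by edgeR, 3 of 3 sections), and its lowest level was in region 1, at 15.1 ± 1.5 CPM. Among genes at 50 CPM or more, gene-Evo08716 decreased most and had 158 ± 21 CPM against 481 ± 112 (log2 difference -1.50 ± 0.14 SE, adjusted p = 2.58e-19 by edgeR, 3 of 3 sections). Its mean level declined from 841 CPM in region 1 over 437, 395 and 250 CPM in regions 2, 3 and 4. Without section 1, 217 genes were called in region 5. With library size alone 588 were higher and 110 lower, 84.2% against 36.3%.

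**Figure D3:**
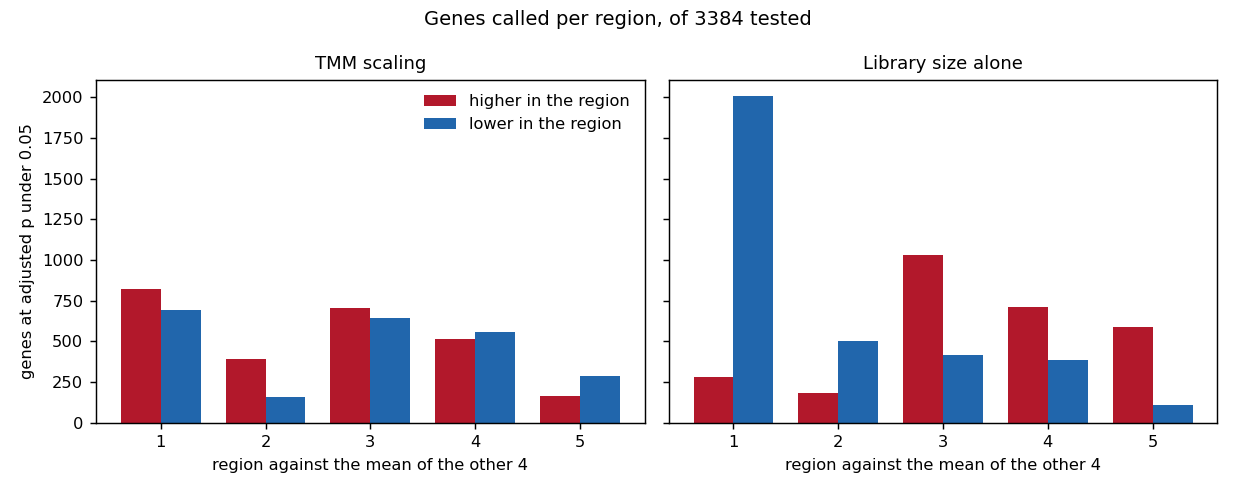
Numbers of genes at an adjusted p under 0.05 (edgeR), higher (red) or lower (blue) in each region against the mean of the other 4, with TMM scaling and with library size alone. In region 1 the higher genes number 820 with TMM and 279 with library size alone.

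**Figure D4:**
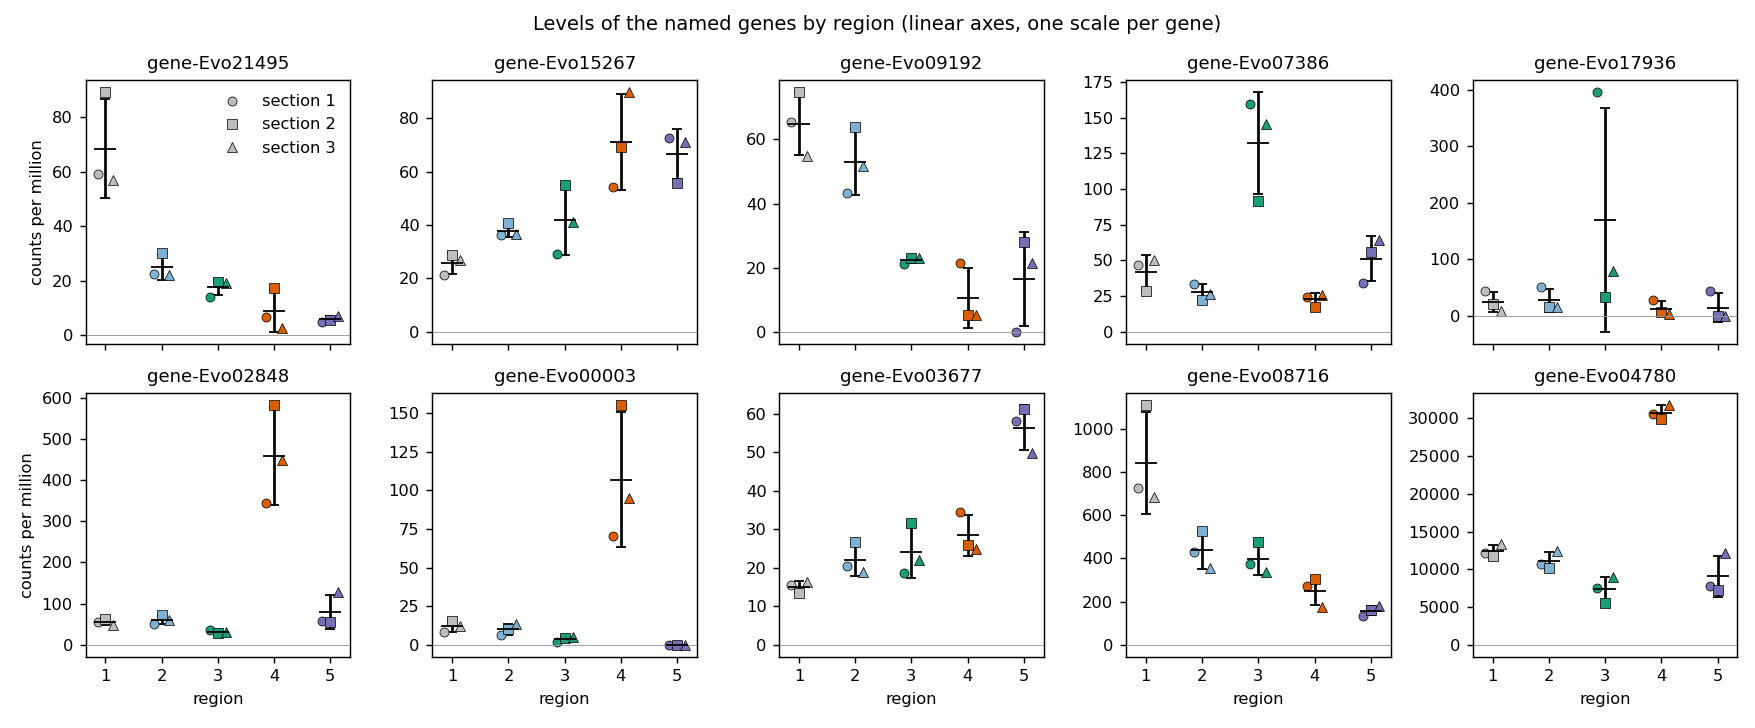
TMM-scaled CPM of the first-ranked tested genes in the 5 regions, on linear axes with a scale of their own. Points are the 3 sections and black bars the mean ± SD; gene-Evo02848, gene-Evo00003 and gene-Evo04780 stand highest in region 4, at 458, 107 and 30741 CPM.

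Spatial structure was also measured gene by gene, without regions, by Moran's I, which is near 0 for a random arrangement and rises when adjacent spots have similar levels. Of 4417 genes with a UMI in at least 5% of the tissue spots of every section, 124 (2.81%) had an I of at least 0.1 in all 3 sections. After 20 shuffles of the spots the count was 0 each time, with a highest I of 0.055. The most structured gene, gene-Evo04780, had an I of 0.518 ± 0.046. Its TMM-scaled level among the tested genes was 30741 ± 961 CPM in region 4 and 12417 ± 860 in region 1. It was 11088 ± 1228 in region 2, 7345 ± 1698 in region 3 and 9077 ± 2728 in region 5. In CPM of all genes its mean over sections was 6096. The log2 difference of region 4 from the rest was 1.67 ± 0.05 SE (adjusted p = 3.39e-95 by edgeR, 3 of 3 sections). The structured genes were mostly abundant, since 111 of the 124 were among the 442 most abundant genes. Of 2140 genes not called structured and tested between regions, with a median of 53.7 in CPM of all genes, 1593 (74.4%) differed. So 2.81% is the share past this size rule, not the share of genes that vary over the tissue.

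Of the 124 structured genes, 63 had not been used for clustering and were tested between regions, and all 63 differed. So did 166 of 167 genes (99.4%) that were not structured but among the 442 most abundant, so this share does not set the structured genes apart. By fitted difference, without a test of the order, the highest level was in region 1 for 35 of the 63, region 3 for 13, region 4 for 10, region 5 for 4 and region 2 for 1. In region 1, 39 were higher and 15 lower than in the mean of the rest, and in region 4, 13 were higher and 43 lower. In region 3, 23 were higher and 30 lower, in region 5, 7 and 45, and in region 2, 34 and 11. Over all tested genes, 820 were higher and 694 lower in region 1, and 515 and 556 in region 4. Directions were not compared with those of equally abundant genes that were not structured. They are also relative to TMM: library size alone moved the median log2 difference of all genes by -0.39 in region 1 and 0.27 in region 5. The count of structured genes was 270 at a threshold of 0.05 and 31 at 0.2.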

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

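The limits of both tests in this part were set after a map of UMIs over the array had been seen and before the tested values were computed. Spots outside tissue, which enter no comparison, held 6.18%, 6.999% and 6.62% of all UMIs in sections 1, 2 and 3, above the 3 counts that a count of 0 allows. Across genes with at least 50 CPM in tissue, their profile correlated with that of tissue spots at Pearson's r of 0.984, 0.984 and 0.986 in log2 CPM, and under 0.3% of these genes differed more than 2-fold. Tissue missed when spots were assigned would leave many rich spots, but only 0.518%, 0.423% and 1.08% of outside spots reached the lower quartile of tissue UMIs, under the limit of 2% in every section, which argues against it. Spread of transcripts from the tissue needs a decline with distance: the median was 733, 801 and 709.5 UMIs beside the tissue and 125, 191 and 134 at 5 or more spots away, ratios of 5.86, 4.19 and 5.29, so spread remains a candidate explanation. No biological explanation was tested, and the same spread between spots over tissue was not measured.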

How the results depend on the processing

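Thinning before clustering, interior spots, library size alone, leaving out region 5 and the 2 settings that removed spots under 500 UMIs in section 3 or for Moran's I were chosen after seeing the data. Of 103 alternative counts of genes, 88 were within 1.5 times the reported count. Descriptions of regions (share of spots, median UMIs, and the angle and contacts of regions 3 and 4) varied more. Of 92 alternative values, 37 moved by more than 1 SD over sections. Genes differing between regions numbered 1634 to 3343 in 17 alternatives against 2213; the 3343 came from dividing UMIs between clustering and testing, which tested 6156 genes, 54.3% of them called, and the same setting gave 2158 in region 3 and 1952 in region 4. Leaving out each section in turn gave 1839 to 1856 genes between regions, 285 to 446 in region 2, 707 to 913 in region 4 and 217 to 377 in region 5, fits with fewer samples. Region 2 gave 160 genes without the section block, 350 with DESeq2, 1673 at resolution 0.2 and 1276 after thinning; in the last 2 its best match was also that of region 1. Library size alone gave 2286 genes in region 1 and 698 in region 5. Structured genes numbered 270 and 31 at thresholds of 0.05 and 0.2, by construction. The causes of the other changes were not tested. The block changed no other count by over 1.5 times, and of the named genes only gene-Evo17936 in region 4 lost its call. Without section 1 its log2 difference was -0.49, against a mean that included region 5 at 0 CPM in sections 2 and 3. With region 5 left out of the fit over all sections, which still held section 1, it was -1.97 and the call was kept. Without the block it was -1.65, near the reported -1.57, with a weaker p-value. The other 144 of 146 alternative fold changes kept their direction and call, but sizes varied: log2 differences ran from 2.73 to 5.47 for gene-Evo00003 in region 4, 0.68 to 2.03 for gene-Evo09192 in region 2, 1.89 to 2.56 for gene-Evo21495 and -1.43 to -0.44 for gene-Evo15267 in region 1, the last with adjusted p of 3.46e-13 to 0.0479. The section 3 spots under 500 UMIs all lay in region 6, which was not tested, so leaving them out could change no fit. That setting is not counted among the alternative gene counts between regions or fold changes. Alternatives for gene lists, their co-location and their share of UMIs were not run, since no identifier has a symbol, and regions with an overlap under 0.3 gave no value. Depth limits rare genes: 3384 of 11611 genes for testing passed the count filter.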

Other observations

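The tests of thinned spots by their share in 1 region and by equal UMIs, the fit without region 5 and both tests of low-yield positions were chosen after their results had been seen, and the other tests of region 4 after maps of UMIs and regions had been seen but before their values were computed. Chance agreement between sections as the source of the differences between regions was tested by relabelling the summed counts within sections. There were 100 arrangements, with the real one included. For all regions together, 1 of 100 arrangements called 2213 genes or more, the real one, and the highest other called 1515. For region 1, 1 of 100 reached 1514 genes (highest other 959), for region 3, 1 reached 1349 (highest other 833) and for region 4, 1 reached 1071 (highest other 764). For region 2, 4 of 100 reached 551 genes, the highest other being 1208, and for region 5, 3 of 100 reached 455, the highest other being 592. The arrangement with 1208 genes gave the label of region 2 to region 1 in all 3 sections, so it compared another real region. The 592 genes came from a mixed label, region 3 in sections 1 and 2 and region 5 in section 3. The median over the other arrangements was 0 for every result. The tested genes were not used to cluster, so this argues against chance agreement between sections in these genes. Sections were clustered together, and shuffled labels mix real regions, which raises the residual variation and lowers their calls. Whether the grouping of spots itself arose by chance is therefore not decided by this test.

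Region 4 stood apart in UMIs per spot, and the tissue edge and the UMI total were tested as technical explanations of the grouping and calls of its spots. Among interior spots 1176 genes were called in region 4, against 1071 over all spots and 1438 in a fit of the same form without region 5. Of the 1438, 1132 were called again in the same direction. The median absolute log2 change of the 1428 of them tested in both fits was 0.52 against 0.55. Only 17.4% ± 5.1 of region 4 spots had an adjacent position off tissue, so both fits shared most spots and similar values were likely. This argues against spots at the outermost edge as the source of the calls. An effect of the edge further inward was not tested. With every spot thinned to equal UMIs, the Jaccard overlap of region 4 with its best match was 0.469, between the limits of 0.3 and 0.5 set before this value was computed, which decided nothing. After thinning, 86.1% of region 4 spots fell in 1 region, against 7.15% of other spots. So did 71.4%, 70.8% and 74.1% of region 5 spots in sections 1, 2 and 3, so regions 4 and 5 merged. Spots of other regions with UMIs within the quartiles of region 4 did so in 9.15%, 9.93% and 11.3%, at most 0.126 of the share of region 4. Among them, region 5 spots did so in 71.4%, 78.8% and 69.6%, and those of regions 1, 2 and 3 in at most 18.2%. The thinned counts are part of the UMIs that had placed these spots outside region 4, so a lower share was likely. Whether the UMI total alone explains the grouping is therefore not decided. A tissue structure in the lines of region 4 remains a hypothesis, since no stained image or annotation was used and cell density was not measured.

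At 13 array positions the UMI count was under 0.3 of the median of adjacent positions in all 3 sections, and these positions held 7, 8 and 6 of the spots of region 6 in sections 1, 2 and 3. Chance overlap is not an explanation: the sections had 18, 23 and 25 such positions, and 1000 random placements gave at most 0 shared ones against 13. A candidate explanation is that a barcode which can pair with the read 1 handle, the sequencing primer site that every capture oligonucleotide shares, is copied or read poorly. Of the 13 barcodes, 10 shared at least 6 bases with the reverse complement of the handle, as did 3.69% of all barcodes. The median yield of all 184 such barcodes was 0.854, 0.845 and 0.869 of their neighbours, between the limits of 0.7 and 0.9. By these limits the explanation stays open. Barcodes sharing as many bases with the handle itself had 1.01, 1.04 and 1.02. With the reverse complement, the median yield fell as more bases were shared. It was 1.03, 1.03 and 1.03 at 3 or fewer bases and 0.726, 0.698 and 0.753 at 7 or more, in sections 1, 2 and 3. With the handle itself, 7 or more shared bases gave 1.01, 0.996 and 1.03. The explanation therefore remains a candidate, and no biological explanation was tested.

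In CPM of all genes, gene-Evo17936 had 57.9 over the whole of section 1 and 9.73 and 11.4 in sections 2 and 3. Of 2506 genes with at least 50 CPM in some section, it alone was more than 2-fold higher in 1 section than in both others. Another gene was more than 2-fold lower in section 1 than in both others. In section 3, 37 of the 39 spots of region 6 held under 500 UMIs.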
